A study of Homo sapiens with 14 samples.

How the data were processed

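The samples were human foreskin fibroblasts, untreated, after 6 days of reprogramming small molecules (D6) and at day 11 after further culture with cardiac inductive molecules (D11). Groups were taken from the sample titles. Per the labels' protocols, chromatin was cross-linked with formaldehyde, precipitated with a Magna ChIP G kit, sonicated, amplified by 19 cycles of PCR and sequenced on an Illumina HiSeq. The marks were H3K4me3, H3K27ac and H3K27me3, with 1 library per mark and time. The 5 input libraries entered only as the background of the peak lists. Per the labels, 1 input served fibroblast H3K4me3 and H3K27ac, another fibroblast H3K27me3, 1 D6 H3K4me3, 1 D6 H3K27ac and H3K27me3, and 1 all 3 marks at D11.

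Per the submitters' processing notes, CASAVA 1.8.4, Bowtie 1.1.0, SAMtools 0.1.19, MACS and MACS2 were used with the genome build hg19. Per the file headers, reads were unique and free of duplicates, and peaks were called per library against an input. H3K4me3 and H3K27ac peaks came from MACS 1.4.2 with a p cutoff of 1e-05, and H3K27me3 peaks from the broad mode of MACS 2.0.9 with a q cutoff of 0.01, per the file headers. The larger of each pair of libraries was scaled towards the smaller, per the file headers. The fibroblast H3K4me3 and H3K27ac headers shared 1 chromatin name and the fibroblast H3K27me3 header carried another, so the headers do not show that the marks of untreated cells came from 1 preparation. Peaks of H3K27me3 are not comparable in width or number with those of the other marks, since another caller version and setting made them.

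The deposited count per peak is the number of tags of the immunoprecipitated library inside the peak, without normalization, and was given for H3K4me3 and H3K27ac. The deposited score of those lists is the −log10 of the caller's p-value multiplied by 10, which reaches a ceiling for the strongest peaks. The authors' H3K27me3 lists give the −log10 of the p-value and of the q-value, and the pileup signal at the summit. The deposited fold enrichment is a ratio of the immunoprecipitated library to the caller's local background. It is the authors' value and was used only to rank or describe peaks within a list. The authors' lists also give a false discovery rate in percent, which was not used here. Peak widths are in bp, as the deposited files give them.

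Depth per library was read from the file headers as the number of filtered tags. It ranged from 6946917 for fibroblast H3K27ac to 45371092 for D6 H3K27ac, and the inputs held 23338987 to 48926746 tags. Depth can change the number and width of called peaks, but neither followed depth in every mark, so list sizes, covered lengths and median widths are given beside each other. Lists were called separately, and the lists were compared without scaling between times. Tags or pileups were scaled between libraries only to ask whether peaks of 1 list could have been seen in another, by the summed tags of shared peaks, by their median density for tags per kb, and by the caller's depth for pileup.

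Peak lists were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. A peak was gained if it shared no base with a peak of the same mark at the earlier time, and lost if it shared none at the later time. Chromosomes 1 to 22 and X were used. Y and a 100-kb window of X were left out because the cells came from donors, and no single region on X is named. The overlap by chance is the mean of 100 random placements of peaks on their own chromosomes within the span the lists cover. Shares have Wilson intervals. The overlap code was tested on simulated lists, where it recovered every kept, gained and lost peak in 3 of 3 marks, and gave the same counts as bedtools 2.31.1 in 9 of 9 comparisons of the real lists.

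Overlaps within a mark, peak counts and their alternatives were fixed before the data were examined. The bounds of 5 tests of technical explanations were written before the results of those tests were seen. The alternatives were at least 50% of the peak covered, a caller's p of at most 1e-10 in both lists, equal numbers of the most significant peaks per mark, and merging of peaks within 1 kb. The rule for named regions was the 3 gained and the 3 lost at D11 per mark with the highest fold enrichment. Joined clusters of H3K27me3 peaks, windows of 100 kb, tag densities and the requirement of p 1e-10 in the changed list alone were chosen after the data had been examined.

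Gene models of hg19 were not used here, so no region is assigned to a gene, exon or promoter, and the planned counts over promoters and over 22 gene lists were not run. H3K27ac peaks were instead called distal when more than 1 kb from every H3K4me3 peak of the 3 times, or 2.5 kb as the alternative. The marks were compared over H3K27me3 regions in place of promoters. Both substitutes were chosen after the data had been examined.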

Results

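Histone marks were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in human foreskin fibroblasts taken through a small-molecule protocol for cardiac reprogramming. Cells were sampled as untreated fibroblasts, after 6 days with reprogramming small molecules (D6), and after another 5 days with cardiac inductive molecules (D11). Trimethylation of histone H3 at lysine 4 (H3K4me3) is typical of active promoters, and acetylation at lysine 27 (H3K27ac) of active promoters and enhancers. Trimethylation at lysine 27 (H3K27me3) is placed by Polycomb complexes and is typical of repressed genes. The series holds 14 samples, of which 9 are immunoprecipitated libraries with a peak list, 1 for each mark and time, and 5 are inputs. There were no replicates, so no p-value was computed, and a difference between times is a difference between 2 libraries. Intervals in brackets are 95% Wilson intervals and cover counting error only. They treat peaks as independent, although neighbouring peaks may not be.

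The H3K4me3 libraries held 29269491 tags in fibroblasts, 17515799 at D6 and 29377191 at D11. The H3K27ac libraries held 6946917, 45371092 and 11696178 tags in the same order, and the H3K27me3 libraries 34759910, 15650762 and 28235033. The share of tags inside peaks rose for H3K4me3 from 18.6% in fibroblasts to 30.4% at D6 and 37.6% at D11. For H3K27ac that share was 16.8%, 17.5% and 18.1%. The H3K27me3 files gave no tag counts per peak.

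The first comparison asked how the active promoter mark changed over the protocol. Most H3K4me3 peaks of fibroblasts were still called at D11, and the D11 list held further peaks. Of 18002 fibroblast peaks, 17391 (96.6%, 96.3 to 96.9) overlapped a D11 peak and 611 did not. Of 19848 D11 peaks, 4519 (22.8%) overlapped no fibroblast peak. Random placement of the peaks on their chromosomes gave an overlap of 3.83% of fibroblast peaks. The gained D11 peaks had a median fold enrichment of 7.96, against 52.25 for D11 peaks already present in fibroblasts, as the authors' caller scored them within the D11 list. H3K4me3 peaks also covered more sequence, 36.6 Mb in fibroblasts, 40.2 Mb at D6 and 56.9 Mb at D11, with median widths of 1868, 1978 and 2571 bp. The share of tags inside peaks (18.6%, 30.4% and 37.6%) and the caller's fragment length (208, 213 and 254 bp) rose in the same order. How far a lower enrichment of the fibroblast library accounts for the further peaks and length was not settled.

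The lists differed by D6 already. Between fibroblasts and D6, 2701 H3K4me3 peaks were gained and 656 lost, and between D6 and D11, 3260 were gained and 1232 lost. After the 3 lists were joined into 21306 regions, 14984 (70.3%, 69.7 to 70.9) were occupied at all 3 times and 2971 (13.9%) at D11 alone. Of 2462 regions new at D6, 1540 (62.6%, 60.6 to 64.4) were present at D11 as well. Both comparisons used the same fibroblast list, so a site missed in that list counted as new at both later times. When gained and lost peaks had to pass a p of 1e-10 while being absent from the other list at the authors' threshold, 2837 gains and 202 losses remained between fibroblasts and D11. Of the 4519 gained peaks, 16.0% held enough tags, scaled by shared peaks, to reach the lower quartile of the fibroblast list, and 52.6% to reach its lowest 5%. With equal numbers of peaks per list there were 3019 gains and 950 losses over that step.

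The 3 gained H3K4me3 peaks with the highest fold enrichment at D11 lay on chromosome 10 at 82167123 to 82171535, chromosome 12 at 113344093 to 113347985 and chromosome 19 at 45942405 to 45943824 (all positions in hg19). Their fold enrichments at D11 were 71.28, 62.25 and 59.7, and each was also a peak at D6. The chromosome 10 region overlapped an H3K27me3 peak in fibroblasts and an H3K27ac peak at D11 alone. The chromosome 12 and chromosome 19 regions overlapped no H3K27me3 peak and already had H3K27ac peaks in fibroblasts, with fold enrichments of 32.85 and 10.46. The 3 lost peaks with the highest fibroblast enrichment lay on chromosome 4 at 8594024 to 8596163, chromosome 2 at 218805862 to 218809200 and chromosome 19 at 14048160 to 14049641. Their fold enrichments in fibroblasts were 44.16, 37.25 and 35.04. The chromosome 2 peak was absent at D6 already, while the other 2 were still called there.

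**Figure D1:**
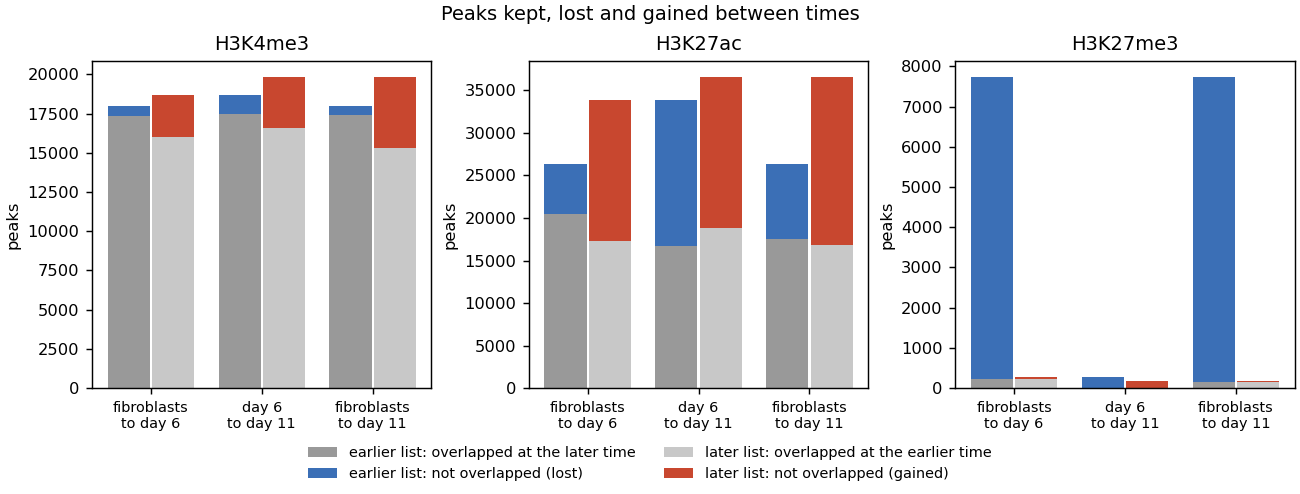
Number of peaks (vertical axis) per mark in each pair of times (horizontal axis). Left bars show the earlier list, split into peaks overlapped at the later time (dark grey) and lost peaks (blue), and right bars the later list, split into peaks overlapped at the earlier time (light grey) and gained peaks (red). H3K4me3 peaks were mostly kept, H3K27ac lists, from libraries of unequal depth, shared fewer of their peaks, and 7603 of 7744 fibroblast H3K27me3 peaks were not found at D11.

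The second comparison asked how active promoters and enhancers, read from H3K27ac, changed. The lists of this mark differed far more between times than those of H3K4me3. Its libraries also differed more in depth. Fibroblast H3K27ac peaks held a median of 26 tags, against 223 for fibroblast H3K4me3, and how far missed weak peaks add to the exchange was not tested. Of 26334 fibroblast H3K27ac peaks, 17535 (66.6%, 66.0 to 67.2) overlapped a D11 peak and 8799 did not, and of 36620 D11 peaks, 19743 (53.9%) overlapped no fibroblast peak. By D6, 16650 peaks had been gained and 5854 lost. Of 54562 joined H3K27ac regions, 13030 (23.9%) were occupied at all 3 times, 13175 (24.1%) at D6 alone and 15359 (28.1%) at D11 alone. Of 16561 regions new at D6, 3386 (20.4%, 19.8 to 21.1) were present at D11, a lower share than the 62.6% for H3K4me3. Depth limits this comparison, since tags fell from 45371092 at D6 to 11696178 at D11 for H3K27ac and rose from 17515799 to 29377191 for H3K4me3. Of the 13175 regions at D6 alone, 46.2% held enough tags, scaled by shared peaks, to reach the median of the D11 list. By tags per kb that share was 31.0%.

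Between D6 and D11, 17770 H3K27ac peaks were gained and 17258 lost. More peaks were lost than gained over that step under all 5 alternative settings, the smallest excess being 534 peaks and the largest 3178. The D6 library had the most tags of the 3 and its peaks were wider, with a median of 2373 bp against 1208 bp in fibroblasts and 1445 bp at D11. Its peaks covered 98.5 Mb, against 39.4 Mb and 65.5 Mb. With equal numbers of peaks per list, 11963 peaks were gained and 10954 lost from fibroblasts to D11, so the excess of gains was 1009 peaks, against 10944 with the lists as deposited. With p 1e-10 asked of the changed peak, 9649 were gained and 3229 lost.

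Gained H3K27ac lay mostly away from H3K4me3. A peak was counted as distal when it lay more than 1 kb from every H3K4me3 peak of the 3 times, which stands in for distance from promoters. Distal peaks were 50.9% (50.3 to 51.5) of the fibroblast list, 68.8% (68.3 to 69.3) of the D6 list and 62.2% (61.7 to 62.7) of the D11 list. These shares ranked as the depth of the libraries did, at 6946917, 45371092 and 11696178 tags, so an effect of depth was not excluded. With equal numbers of peaks per list, 10140 distal peaks were gained and 8055 lost from fibroblasts to D11. The excess of distal gains was then 2085, against 9750 with the lists as deposited. Equal list sizes draw total gains and losses together by construction, so this fall does not measure the net distal change. Of the distal D11 peaks, 16457 of 22794 (72.2%, 71.6 to 72.8) were absent in fibroblasts, against 3286 of 13826 (23.8%, 23.1 to 24.5) of those near H3K4me3. Of the distal fibroblast peaks, 6707 of 13401 (50.0%) were lost by D11, against 2092 of 12933 (16.2%) near H3K4me3. At D6, 15265 of 23329 distal peaks (65.4%) and 1385 of 10594 peaks near H3K4me3 (13.1%) were gained relative to fibroblasts. Losses by D6 differed less, at 25.7% of distal fibroblast peaks and 18.6% of those near H3K4me3. At p 1e-10, distal peaks were the smaller part of the D6 losses, 1573 of 3594 with both lists at that p and 891 of 1851 with the changed list alone.

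The gained H3K27ac peaks with the highest fold enrichment at D11 lay on chromosome 12 at 47291352 to 47300296, chromosome 17 at 63509944 to 63513859 and chromosome 3 at 143045391 to 143057802. Their D11 fold enrichments were 61.36, 47.8 and 47.14. The first of these was also enriched at D6, at 50.76, and the chromosome 17 peak at 17.38, while the chromosome 3 peak was called at D11 alone. Among lost peaks, the highest fibroblast enrichments were 61.0 on chromosome 19 at 41151926 to 41153502, 58.91 on chromosome 2 at 102742802 to 102745969 and 56.69 on chromosome 15 at 39763390 to 39766935. All 3 were still called at D6, at 23.32, 23.43 and 42.14.

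The third comparison asked what happened to the repressive mark. Nearly all called H3K27me3 was gone from the lists of treated cells. Fibroblasts had 7744 peaks over 3.73 Mb, D6 had 275 peaks over 0.0725 Mb and D11 had 173 peaks over 0.0447 Mb, which is 28.2-fold and 44.8-fold fewer peaks than in fibroblasts. Only 227 fibroblast peaks (2.93%, 2.58 to 3.33) overlapped a D6 peak and 141 (1.82%, 1.55 to 2.14) a D11 peak. Of the later peaks, 219 of 275 at D6 (79.6%) and 141 of 173 at D11 (81.5%) overlapped a fibroblast peak, and 89.8% and 94.2% lay within 1 kb of one. Of the 275 D6 peaks, 8 (2.91%, 1.48 to 5.63) overlapped a D11 peak, and 165 of 173 D11 peaks overlapped no D6 peak. Random placement gave 0.00364%, but it ignores that most peaks of both later lists lay at fibroblast peaks. Of all fibroblast peaks, 1.82% overlapped a D11 peak, which is the closer reference. Fibroblast regions found again at both later times numbered 11, against 4.13 if the later lists were independent. Fibroblast peaks in the top quartile of fold enrichment were found again at D11 in 4.13% of cases, against 1.14% in the bottom quartile. The quartiles between, in rising order, gave 0.826% and 1.19%, so only the top quartile stood apart. The fibroblast H3K27me3 library carried another chromatin name in its file header than the other 2 fibroblast libraries, and a lower yield of the later immunoprecipitations was not excluded. Scaled to the later depth, 10.5% of fibroblast peaks would reach the median pileup of the D6 list and 55.9% that of the D11 list. By that limit, depth could account for most of the loss at D6, though the 2.93% found there was below the 10.5%. With p 1e-10 asked of the changed peak, 3420 H3K27me3 peaks were lost by D11 and 7 gained.

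The lost H3K27me3 peaks with the highest fibroblast enrichment lay on chromosome 1 at 1951204 to 1952222, chromosome 21 at 38080382 to 38081343 and chromosome 2 at 73518774 to 73520450. Their fold enrichments were 16.7, 16.7 and 16.45. The chromosome 2 region carried H3K4me3 peaks at D6 and D11 that fibroblasts lacked. The gained D11 peaks with the highest enrichment lay on chromosome 13 at 112720645 to 112720851, chromosome 1 at 91178883 to 91179103 and chromosome 11 at 32462306 to 32462590. Their widths were 207, 221 and 285 bp and their fold enrichments were 9.08, 8.13 and 8.13.

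The last comparison set the marks against each other at the same regions. H3K4me3 appeared over many regions that had carried H3K27me3 in fibroblasts. An H3K4me3 peak overlapped 671 of the 7744 regions in fibroblasts (8.66%, 8.06 to 9.31), 1281 at D6 (16.5%, 15.7 to 17.4) and 3057 at D11 (39.5%, 38.4 to 40.6). Random placement gave 1.72%, 1.87% and 2.53%. The regions had a median width of 349 bp and joined into 2763 clusters at a gap of 10 kb, 1 of them holding 72 regions. A wide H3K4me3 peak could therefore count at several regions, and the intervals, which treat regions as independent, are too narrow. Of 7073 regions without H3K4me3 in fibroblasts, 719 (10.2%) had it at D6 and 2414 (34.1%, 33.0 to 35.2) at D11, and 682 of the 719 kept it to D11. Of 671 regions with peaks of both marks in fibroblasts, 28 had no H3K4me3 at D11. The headers of these 2 fibroblast lists carried different chromatin names, so they do not show that both marks came from 1 preparation. Among all H3K4me3 peaks gained between fibroblasts and D11, 1181 of 4519 (26.1%, 24.9 to 27.4) lay within 1 kb of fibroblast H3K27me3, against 735 of 15329 peaks present at both times (4.79%, 4.47 to 5.14) and 19 of 611 lost peaks (3.11%). Whether the fibroblast H3K4me3 library would have shown these peaks at an equal enrichment was not settled, since its share of tags in peaks was 18.6% against 37.6% at D11.

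H3K27ac followed at few of these regions. It overlapped 10 of the 7744 regions in fibroblasts and 10 at D6 (0.129% each, 0.0702 to 0.238), below the 1.91% and 4.16% of random placement. At D11 it overlapped 286 (3.69%, 3.30 to 4.14), against 3.02% by random placement. Of 281 regions that gained H3K27ac by D11, 256 (91.1%, 87.2 to 93.9) also carried H3K4me3 at D11. Neighbouring regions are not independent here either. A single cluster of 72 regions on chromosome 17 had 65.7 kb of H3K27ac at D11 over a span of 83.6 kb. A few loci could therefore account for the excess over random placement and weigh on the 91.1%, and the intervals are too narrow. The gained D11 H3K4me3 peaks overlapped H3K27ac in 11.4% of cases in fibroblasts, 13.1% at D6 and 26.6% (25.4 to 28.0) at D11. Those present at both times did so in 62.5%, 56.3% and 63.4% of cases.

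**Figure D2:**
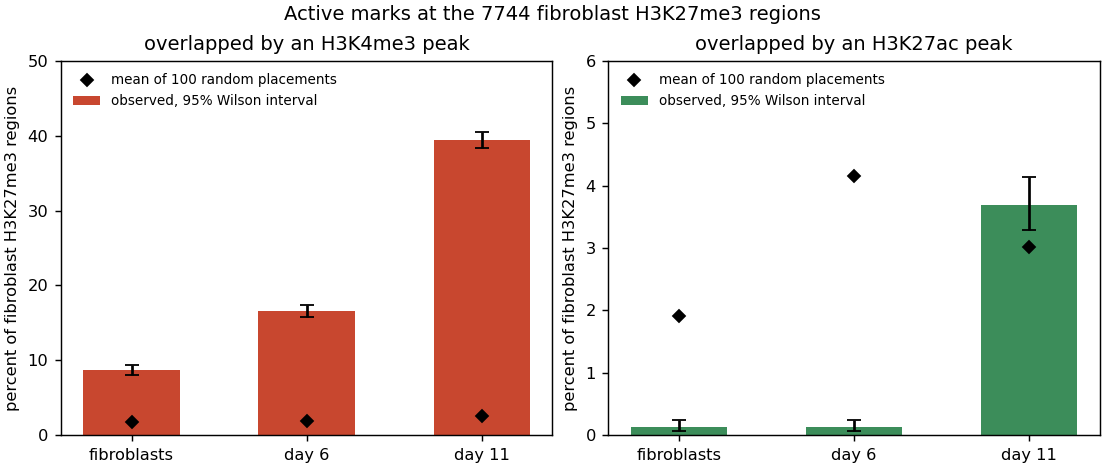
Percent of the 7744 fibroblast H3K27me3 regions (vertical axes, on different scales) overlapped by H3K4me3 (left) or H3K27ac (right) at each time. Bars show the share with its 95% Wilson interval, and diamonds the mean of 100 random placements. The H3K4me3 share was 8.66% in fibroblasts and 39.5% at D11, and the H3K27ac share was 0.129% and 3.69%.

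H3K4me3 rose within clusters of H3K27me3 regions, to very different extents. Fibroblast H3K27me3 peaks within 10 kb of each other were joined into 2763 clusters, a rule set after the data had been examined. At D11, 1398 clusters held more H3K4me3-covered sequence than in fibroblasts, 34 held less, 1239 had none at either time and 92 had the same length to the base pair. H3K4me3 within the clusters covered 472 kb in fibroblasts, 918 kb at D6 and 2447 kb at D11. These lengths are sums over separately called peaks and move with how much was called, which rose over the genome too. The clusters spanned 8.44 Mb, so most of their length had no H3K4me3 peak at D11.

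The cluster with the most H3K27me3 lay on chromosome 17 at 46640778 to 46724370 and spanned 83.6 kb, with 51.5 kb of H3K27me3 in fibroblasts. There H3K4me3 covered 1.27 kb in fibroblasts, 4.32 kb at D6 and 75.8 kb at D11. H3K27ac covered none of it in fibroblasts or at D6 and 65.7 kb at D11. H3K27me3 covered 1.05 kb at D6 and none at D11. A cluster on chromosome 2 at 176992647 to 177055313 changed in the same direction, with 4.86, 9.50 and 31.0 kb of H3K4me3, and 22.5 kb of H3K27ac at D11 alone. In some other large clusters H3K4me3 rose without H3K27ac. On chromosome 13 at 100607178 to 100650880 it covered 0 kb, 3.07 kb and 14.1 kb, and on chromosome 11 at 31818583 to 31850518 it covered 0 kb, 2.36 kb and 9.90 kb. Neither had H3K27ac at any time. On chromosome 17 at 46794734 to 46838991, H3K4me3 went from 2.30 kb in fibroblasts to 6.51 kb at D11, with 0.916 kb, 2.19 kb and 2.83 kb of H3K27ac at the 3 times. On chromosome 8 at 11533455 to 11574200, H3K27me3 fell from 19.6 kb to 0.408 kb at D11 while H3K4me3 reached 1.84 kb.

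**Figure D3:**
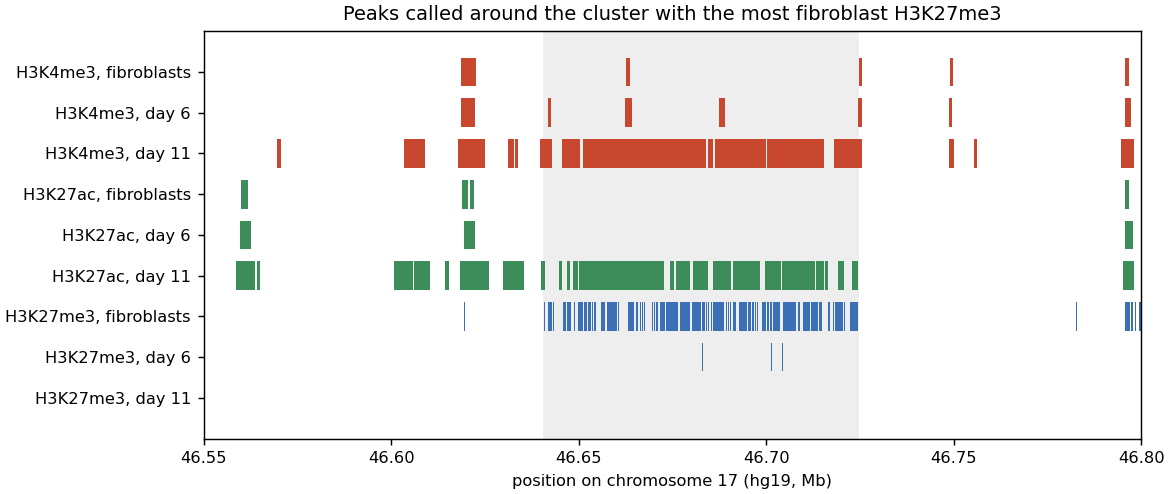
Peaks called in each of the 9 lists (rows) along chromosome 17 from 46.55 to 46.8 Mb in hg19 (horizontal axis). Each box is 1 called peak drawn to scale, and the shaded span is the cluster at 46640778 to 46724370. Fibroblast H3K27me3 peaks covered 51.5 kb of the span, and at D11 H3K4me3 covered 75.8 kb and H3K27ac 65.7 kb of it.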

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

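The results tested were 25 counts of gained, lost or overlapped regions under 118 alternatives. Of these, 67 stayed within 1.5 times the reported count (26 higher, 40 lower and 1 equal) and 51 did not (5 higher and 46 lower). The requirement of p 1e-10 in the changed list alone, and the settings of 1 kb distance, 50% coverage and equal numbers for the H3K27me3 regions, were added after the data had been examined. Equal numbers shrink the longer lists, and p 1e-10 in the changed list alone can only lower a count; the cause of other moves was not tested. The balance of H3K27ac between D6 and D11 turned from 512 more gained to between 534 and 3178 more lost under all 5 alternatives. Its sign therefore depended on the setting, and the alternatives are not independent of each other or of the greater width of D6 peaks. Promoter and gene-list alternatives were not run. Depth limits the comparison of H3K27ac lists, whose libraries ranged from 6946917 to 45371092 tags.

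With p 1e-10 in both lists, lost H3K4me3 peaks were 683 (D6 to D11) and 365 (fibroblasts to D11). H3K27ac losses were 3594 by D6 and 5147 from fibroblasts to D11, and gains 10769 (D6 to D11) and 11685 (fibroblasts to D11). H3K27me3 losses were 3438 by D6, 142 from D6 to D11 and 3483 from fibroblasts to D11, with gains of 72 (D6 to D11) and 21 (fibroblasts to D11). Distal H3K27ac losses were 1573 by D6 and 3581 by D11, and distal gains by D11 were 9512. H3K4me3 then lay on 209, 540 and 1461 of 3536 fibroblast H3K27me3 regions at the 3 times, a D11 share of 41.3%. The D11 share over the fibroblast share was 4.56 as reported, 6.99 at p 1e-10, 5.41 with 50% coverage, 4.15 with equal numbers and 3.21 within 1 kb.

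With equal numbers of peaks, H3K4me3 losses from fibroblasts to D11 were 950 against 3019 gains. H3K27ac gains over the same step were 11963 against 10954 losses, and distal gains 10140 against 8055 losses. The excess of gains was thus 1009 and 2085 peaks, against 10944 and 9750 as deposited. In lists of equal size, total gains and losses of a mark can differ only where 1 peak overlaps several. These balances therefore do not measure net change. H3K27me3 gains were 149 by D6 and 149 by D11, and losses 150 by D6, 170 from D6 to D11 and 152 by D11, with the fibroblast and D6 lists each reduced to 173 peaks, the size of the D11 list. With peaks within 1 kb merged, H3K27me3 losses were 3777 by D6 and 3841 by D11. Within 1 kb, H3K4me3 lay at 1253 fibroblast H3K27me3 regions in fibroblasts, 2088 at D6 and 4023 at D11.

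With p 1e-10 asked of the changed peak alone, H3K4me3 gains and losses were 1162 and 206 by D6, 1851 and 367 from D6 to D11, and 2837 and 202 from fibroblasts to D11. For H3K27ac they were 9834 and 1851, 8884 and 10574, and 9649 and 3229 over the same steps. H3K27me3 gains were 29, 68 and 7, and losses 3349, 141 and 3420. Distal H3K27ac gains and losses were 9064 and 891 by D6, and 8045 and 2415 by D11.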

Other observations

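Windows of 100 kb, chosen after the data had been examined, showed where the active marks spread furthest by D11. The largest rise in H3K4me3 was on chromosome 17 at 46600001 to 46700000, from 5.43 kb in fibroblasts to 70.8 kb, with H3K27ac going from 2.59 kb to 71.4 kb. The next were chromosome 7 at 27100001 to 27200000 (11.2 to 48.8 kb) and chromosome 12 at 54400001 to 54500000 (7.72 to 35.7 kb). H3K27ac rose there too, from 0.607 to 38.4 kb and from 2.90 to 44.0 kb. A window on chromosome 2 at 171500001 to 171600000 had no peak of either mark in fibroblasts and 27.5 kb of H3K4me3 and 31.1 kb of H3K27ac at D11. At D6 the H3K27ac of these 4 windows was 2.97, 1.34, 7.99 and 0 kb. Of the 100 windows with the largest rise in each mark, 17 were in both sets, where independent sets among the 17835 windows with any peak would share 0.561. Fibroblast H3K27me3 was present in 58 of the top 100 H3K4me3 windows and in 9 of the top 100 H3K27ac windows, against 13.2% of all windows with any peak. Both references include windows without H3K4me3 at any time, and the active marks often lie together. Neither is thus a close reference.

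Broad H3K27ac domains without fibroblast H3K27me3 appeared at D11 on chromosome 18 at 10400001 to 10500000 (3.43 kb in fibroblasts, 5.21 kb at D6, 62.1 kb at D11) and chromosome 1 at 118600001 to 118700000 (5.78, 7.11 and 54.0 kb). Others were broad at D6 alone, such as chromosome 15 at 39400001 to 39500000 (17.2, 86.7 and 3.70 kb) and chromosome 9 at 117800001 to 117900000 (7.41, 66.1 and 4.56 kb). Chromosome 7 at 130500001 to 130600000 fell from 38.3 kb in fibroblasts to 9.55 kb at D11. Depth was greatest at D6, and its effect on these lengths was not tested. Chromosome 19 carried 4.43% of H3K27ac peaks in fibroblasts, 2.72% at D6 and 3.30% at D11.

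The tests below were written before their results were seen, except those on tag density, the limit at the lowest 5% and the depth of the D6 H3K27me3 library. H3K4me3 over former H3K27me3 regions was first weighed against the greater number and width of D11 peaks. With equal numbers of peaks, each trimmed to 1 kb at its summit, it overlapped 6.99% (6.44 to 7.58) of regions in fibroblasts and 19.4% (18.5 to 20.3) at D11, a ratio of 2.77, which argues against number and width as the whole cause. A lower enrichment of the fibroblast library was tested by scaling the D11 peaks at these regions by shared peaks: 27.8% (25.2 to 30.6) held enough tags to reach the lower quartile of the fibroblast list, above the bound of 25% set in advance, and 68.7% (65.9 to 71.4) to reach its lowest 5%. Tag counts grow with peak width, and by tags per kb the shares were 11.3% (9.55 to 13.3) and 38.5% (35.6 to 41.4), so lower enrichment was neither shown nor excluded. The treatment, which the design names, also stays open and was not tested.

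The loss of H3K27me3 peaks was weighed against sequencing depth. The caller worked at 28235033 tags at D11 and 25799297 in fibroblasts, and the share of fibroblast regions found at D11 was 0.0325 of the share whose scaled pileup reached the D11 median, which argues against depth at D11. At D6, with 15650762 tags, that ratio was 0.279. Only 10.5% of fibroblast regions would reach the D6 median after scaling, so depth could account for most of the loss there. A lower yield of the D11 immunoprecipitation and a loss of the mark throughout the cells cannot be told apart, since both predict that strong regions are found again more often. The top quartile of enrichment was found again more often than the bottom by a factor of 3.64, while the quartiles between were near the bottom one. No sample in the design separates yield from loss.

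The H3K27ac regions seen at D6 alone were weighed against the depth of that library. After scaling by the peaks shared with D11, 46.2% (45.4 to 47.1) of the 13175 regions held enough tags to reach the median of the D11 list, and 31.0% (30.2 to 31.7) did so by tags per kb. The bound set in advance for depth as the cause was under 10%, so these shares argue against depth for all of the regions, though it could account for the weaker ones. A passing gain of acetylation under the reprogramming molecules, which the design names as the D6 treatment, stays a hypothesis from 1 library.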
